A study of Mus musculus with 6 samples.

How the data were processed

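Spinal cord RNA of 3 mouse genotypes at 2 ages was measured on 6 Affymetrix arrays, 1 per genotype and age. Per the labels' protocols, total RNA from 4 spinal cords was extracted with Trizol, poly(A) RNA was isolated, and biotin-labelled cRNA was hybridised once. The sex of the mice is not given in the sources used here. The deposited values are 1 linear intensity per probe set and array. How the authors summarised probes and scaled the arrays is not given in the sources used here. The table holds 12488 rows, of which 66 are Affymetrix control probe sets. These were left out of the tests and read as quality values.

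Arrays count as already scaled when their 2%-trimmed means lie within 5% of each other or their log2 medians within 0.1. The medians lay within 0.06, so intensities were used as deposited, although the trimmed means differed up to 1.08-fold. Values under the 25th percentile of all values, 31, were raised to it, and log2 was taken. Values at this floor have no order. A probe set was tested when at least 1 array exceeded the pooled median of 79.7, which kept 6737 probe sets. Signal close to the floor limits what can be seen: between 24.6% and 25.9% of the probe sets on each array lay at or under it.

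Gene symbols came from the platform annotation, updated through Entrez identifiers with a reference gene table. Of 12422 probe sets, 10833 had 1 symbol, 396 several and 1193 none here. Of those with 1 symbol, 10817 matched, and 0 symbols changed. Only probe sets with 1 symbol name a gene. The probe set with the highest mean level stands for its gene in lists and among the named genes, giving 5201 genes. Identifiers ending in _f_at, _s_at, _i_at, _r_at or _g_at can cross-hybridise, which applies to the representative probe sets of Cd68, Nnat, Vamp1, Adi1, Coasy, Aqp1, Cyp7b1, Atp2a1, Actb, Zbtb16, Gfap, Mcm3, Zap70, Ighm, Dhh, Sncg, Kif5a, Gabra6, Pvalb, Eif2s3y and Cga.

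The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. The fit had 4 means: disease-free at 75 days, disease-free at 110 days, and the G93A-SOD1 array at each age. The nontransgenic and WT-SOD1 array of an age served as its 2 disease-free arrays, which left 2 residual degrees of freedom (prior degrees of freedom 5.13, prior standard deviation 0.12 on the log2 scale). No group has a replicate of its own, so p-values of this fit measure the spread between arrays of different genotype, not between animals of one group. Each pair of disease-free arrays also held 1 array with higher and 1 with lower levels of the bacterial spike-in controls. The spread thus includes what differed with these levels. WT-SOD1 was compared with nontransgenic on the 4 disease-free arrays with age as a term, on 1 residual degree of freedom, with infinite prior degrees of freedom and hence 1 pooled spread (prior standard deviation 0.19) for every probe set. That spread comes from the contrast of the arrays with higher spike-in levels (nontransgenic 75 days, WT-SOD1 110 days) with the other disease-free arrays, and cannot be told apart from it. SE denotes the moderated standard error of a log2 difference. Fold values are 2 to the power of the log2 difference of floored values. As a count with no test, probe sets were counted on each array that lay at least 2-fold (1 log2 unit) outside the range of 3 disease-free arrays.

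There were 36 gene lists for cell types and processes. Each list has its measured members, the calls over all probe sets and those adjusted over the list alone, and the median log2 difference with its percentile among 10000 random lists of the same size matched on level in 10 bins. Beside it stands the same median for each disease-free array against the other 3. Named genes followed a rule: Sod1 first; the 12 genes farthest above and 8 farthest below the disease-free range at 110 days, and 6 and 6 at 75 days; for age and for WT-SOD1, the 5 up and 5 down with the largest smaller of both same-sign differences; the 5 up and 5 down with the largest change between ages among calls; and from each list up to 4 calls, or 2 values where none passed. Designs, lists, this rule and the main alternatives were set before the data were examined. Cx3cr1, Gabra6, Gh, Pomc and Cga fall outside the rule and were chosen after their values were seen, as were the genes that open the last part of the closing section. Lists of pituitary, cerebellar, glucocorticoid-responsive, clock and Y-linked genes were added later, before the levels of their members were looked at.

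The fits were tested on simulated arrays with the real levels and the spread of the fit with 4 means, drawn independently for each array. In each of 20 simulations per comparison, 200 probe sets were changed, drawn from those with a mean level above the pooled median. The shares below thus do not cover dimmer tested probe sets, such as those of Lyz2 and Hpgd. For G93A-SOD1 at 110 days 9.0% of 1.5-fold, 74.4% of 2-fold and 99.1% of 4-fold changes were recovered, with 5.3% false calls. At 75 days the shares were 10.1%, 77.2% and 99.5%. For the change between ages they were 0.52%, 12.6% and 90.8%, for age 33.3%, 91.6% and 99.1%, and for WT-SOD1 28.9%, 92.0% and 99.8%, the last with 9.3% false calls. Real arrays can share differences that independent noise lacks, and the real WT-SOD1 fit had a larger pooled spread (0.19 against 0.12). These shares may therefore not hold for the real arrays.

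The alternatives were quantile normalization, scaling to 1 median, floors at the 10th and 40th percentile, no filter or a filter on the mean level, each disease-free array left out in turn, an intensity trend in the spread, all disease-free arrays as 1 group, nontransgenic or WT-SOD1 arrays alone as controls, and a WT-SOD1 term. After seeing the data, a term for the arrays with higher bacterial spike-in levels and a fit of the 4 arrays with lower levels were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.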

Results

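Messenger RNA of mouse spinal cord was profiled on 6 oligonucleotide arrays. The arrays covered 3 genotypes at 2 ages. The strain labels read B6SJL for the nontransgenic mice, B6SJL-G93A-SOD1 at 75 days but B6SJL-G93A-SOD1H at 110 days for the G93A-SOD1 mice, and name B6SJL for the WT-SOD1 mice at 75 days, while the WT-SOD1 array at 110 days has none. The nontransgenic mice carried no transgene, the WT-SOD1 mice carried wild-type SOD1, and the G93A-SOD1 mice carried the G93A form of this superoxide dismutase, a form known from familial amyotrophic lateral sclerosis. Per the labels, the RNA of each array came from 4 spinal cords, and each genotype and age had 1 array, hybridised once. The submitters describe G93A-SOD1 mice as free of symptoms at 75 days and as trembling and partly paralysed at 110 days, and WT-SOD1 mice as healthy at both ages. The nontransgenic and WT-SOD1 arrays are therefore called disease-free here. Median intensity per array lay between 77.7 and 80.9, and 6737 probe sets were tested. The number of arrays limits the precision: for G93A-SOD1 and for age, the spread behind the p-values comes from the 2 pairs of disease-free arrays of the same age. Each lone G93A-SOD1 array was assumed to vary like them. For WT-SOD1 against nontransgenic, the spread comes from the change of their difference between ages, pooled over probe sets.

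Sod1, the gene whose transgene defines the groups, was read first. It has 1 probe set on this mouse array, and how far that detects the transgene is not given in the sources used here. Sod1 intensity was 1037 on the nontransgenic array at 75 days and 1498 at 110 days. It was 1583 and 1906 on the WT-SOD1 arrays and 1738 and 1716 on the G93A-SOD1 arrays at 75 and 110 days. All 4 transgenic arrays thus lay above both nontransgenic ones. None of these differences passed the test (WT-SOD1 against nontransgenic, log2 difference 0.48 ± 0.19 SE, adjusted p = 1).

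The first comparison asked which transcripts differed in the diseased spinal cord at 110 days. Genes of microglia and macrophages rose together in G93A-SOD1 cord: Lyz2, encoding lysozyme, was 7.15-fold higher than in disease-free cord of the same age (log2 difference 2.84 ± 0.22 SE, adjusted p = 0.00175). Tyrobp, a signalling adaptor of microglial receptors, was 5.30-fold higher, the lysosomal glycoprotein gene Cd68 4.95-fold, and Cd52 4.89-fold. The genes of the 3 chains of complement C1q rose alike, C1qb 5.13-fold, C1qc 4.28-fold and C1qa 4.21-fold. Mpeg1, encoding a macrophage pore-forming protein, rose 4.60-fold. On the disease-free arrays C1qc read 404 to 472, and on the G93A-SOD1 array 1993.

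Of 27 measured genes of the microglia and macrophage list, 16 rose and 0 fell. Adjusted over the list alone, 21 rose. The list median was a log2 difference of 1.21, above all of 10000 random lists matched on level, while the same median for each disease-free array against the other 3 lay between -0.07 and 0.11. With no filter on level the list median was 0.63. All 27 members were above 0, among them Cx3cr1, a fractalkine receptor of resting microglia, at 0.20 (adjusted p = 0.899). The list of lysosomal, lipid and disease-associated microglial genes had 29 measured members, of which 16 rose and 0 fell (22 adjusted over the list alone), with a median of 0.98. It shared 4 measured members with the first list. Besides Lyz2, Tyrobp and Cd68, its largest rise was that of Cst7, the protease inhibitor cystatin F, at 5.33-fold (2.41 ± 0.18 SE, adjusted p = 0.00138). Of 9 measured complement genes 4 rose, the 3 C1q genes and Clu, encoding clusterin, which rose 1.79-fold (5 adjusted over the list alone, median 0.84, or 0.38 with no filter). Of 20 genes of antigen presentation and the interferon response 4 rose and 0 fell, with 14 rising adjusted over the list alone and a median of 0.55. These were Ifit3 at 2.65-fold, B2m at 2.45-fold, Gbp3 at 2.12-fold and the immunoproteasome subunit gene Psmb8 at 2.05-fold. None of 12 cytokine and chemokine genes passed over all probe sets, and 4 did adjusted over the list alone (median 0.15). Ccl3 had a log2 difference of 0.75 (adjusted p = 0.147) and Tnfrsf1a of 0.71 (adjusted p = 0.130).

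**Figure D1:**
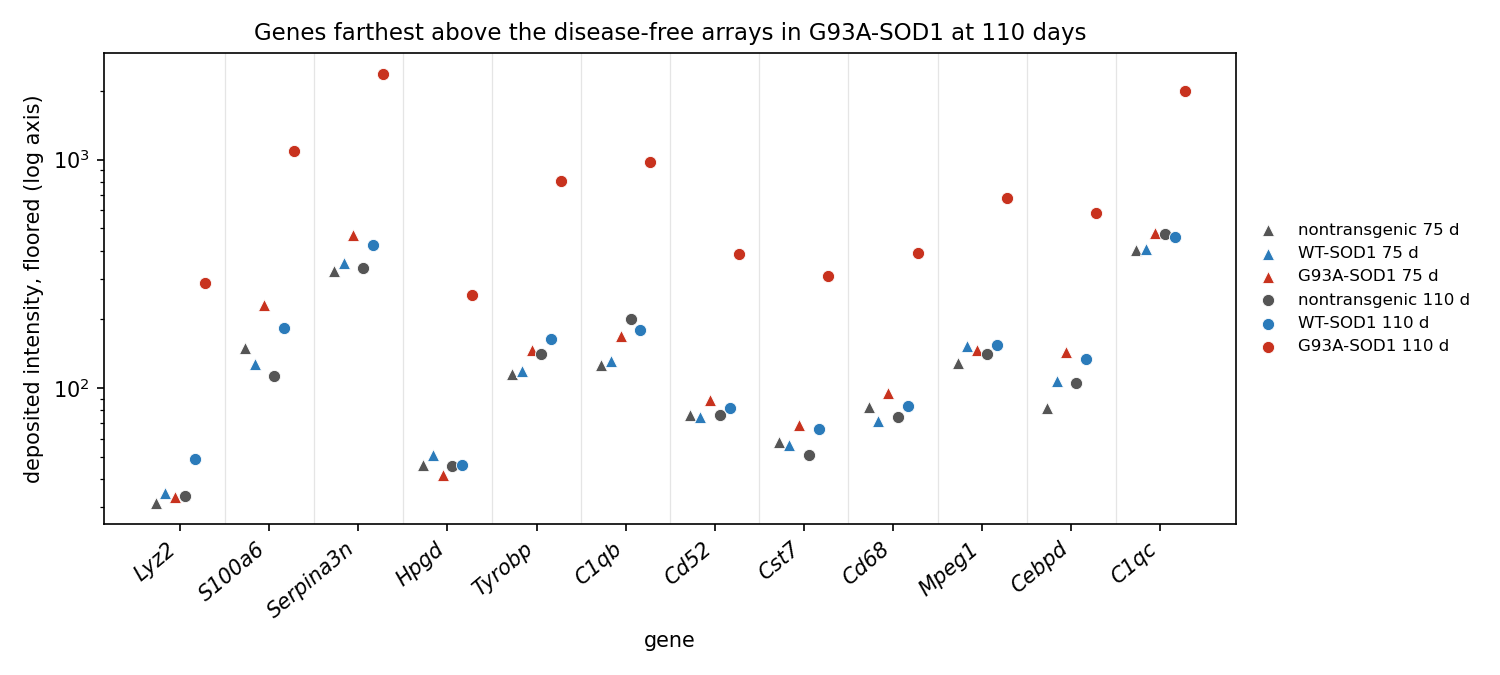
Deposited intensity after flooring (log axis) of the 12 genes farthest above the disease-free arrays at 110 days, 1 point per array, triangles for 75 days and circles for 110 days. On the G93A-SOD1 array at 110 days Lyz2 read 290, against 31.4 to 48.7 on the 4 disease-free arrays, and Serpina3n 2361, against 326 to 422.

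Genes of reactive astrocytes formed the other large group of rises. S100a6, a calcium-binding protein gene, was 7.56-fold higher at 110 days (log2 difference 2.92 ± 0.27 SE, adjusted p = 0.0036). Serpina3n, encoding a secreted protease inhibitor, was 6.29-fold higher, the transcription factor gene Cebpd 4.89-fold, and Emp1 3.37-fold. Of 18 measured genes of this list 9 rose and 0 fell (12 adjusted over the list alone), with a median of 0.86 (0.54 with no filter), and all 18 were above 0. The filter on level can bear on these counts as on those of the microglia list. In the broader astrocyte list 3 of 17 genes rose and 0 fell (4 adjusted over the list alone, median 0.10). These were the fatty acid-binding protein gene Fabp7 at 2.74-fold, the intermediate filament gene Gfap at 2.38-fold (1.25 ± 0.20 SE, adjusted p = 0.0304) and Clu. Hpgd, the prostaglandin-degrading dehydrogenase gene, belonged to no list and rose 5.58-fold (2.48 ± 0.14 SE, adjusted p = 0.000984). Among genes of meninges and fibroblasts 2 of 11 rose, Igfbp2 at 3.19-fold and the proteoglycan gene Fmod at 2.03-fold (median 0.08, but -0.06 without the nontransgenic 110-day array and 0.22 without the WT-SOD1 one). Fmod was also the 1 gene of 25 that rose in the extracellular matrix list (2 adjusted over the list alone, median 0.10). Abca1, a cholesterol exporter gene, rose 2.18-fold and was the 1 call among 25 genes of cholesterol and lipid synthesis, whose median was -0.18 (-0.05 without the nontransgenic and -0.31 without the WT-SOD1 110-day array).

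Neuronal transcripts tended to lie lower, with few calls. Nefm, encoding the medium neurofilament chain, fell by 0.82 on the log2 scale (± 0.13 SE, adjusted p = 0.0301), from 1035 and 986 on the disease-free arrays to 571. Patj, a cell polarity scaffold gene, fell by 0.93 (adjusted p = 0.0191), from 89.6 and 83.2 to 45.2. The farthest gene below the disease-free range was Syt1, the calcium sensor of synaptic vesicle release, at 73.2 against 138 to 232 (log2 difference -1.26 ± 0.32 SE, adjusted p = 0.17). Nnat (-0.95), Btbd3 (-0.94), the kinesin gene Kif5c (-0.85), the vesicle protein gene Vamp1 (-0.70), Adi1 (-0.89) and the carbonic anhydrase-related gene Car8 (-2.15) also lay below all 4 disease-free arrays, each by under 1 log2 unit, and none of them passed the test. Patj and Nefm, too, lay below that range by under 1 log2 unit.

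Of 28 measured neuron and synapse genes 0 passed over all probe sets and 1 fell adjusted over the list alone. The list median was -0.33, below all of 10000 random lists, and the disease-free arrays gave -0.11 to 0.13. It was -0.19 without the nontransgenic and -0.45 without the WT-SOD1 110-day array. In the neurofilament and axon cytoskeleton list 1 of 28 genes fell, Nefm (3 adjusted over the list alone), with a median of -0.29 and disease-free values from -0.09 to 0.16. In the motor neuron list 1 of 14 fell, again Nefm (2 adjusted over the list alone, median -0.16, or -0.05 with no filter). Nefh, the gene of the heavy chain, had a log2 difference of -0.72 (adjusted p = 0.112). Of 15 genes of inhibitory transmission 0 passed (1 fell adjusted over the list alone, median -0.23), with Calb1 at -1.42 and the glycine receptor gene Glrb at -0.58. None of 12 genes of excitatory transmission passed (median 0.06), and Slc1a4 and Tac2 were at 0.35 and 0.32. None of 44 oxidative phosphorylation genes passed (median -0.19, percentile 0.07), with Sdha at -0.44 and Atp5j at -0.38. Markers of other tissue varied on the same arrays. Gabra6, a receptor subunit gene typical of cerebellar granule cells and chosen after its values were seen, read 306 and 327 on the nontransgenic 75-day and WT-SOD1 110-day arrays, 62.7 and 51.8 on the other disease-free arrays, and 38.5 and 39.0 on the G93A-SOD1 arrays at 75 and 110 days. Car8, Calb1 and Zic1 were also highest on these nontransgenic 75-day and WT-SOD1 110-day arrays.

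**Figure D2:**
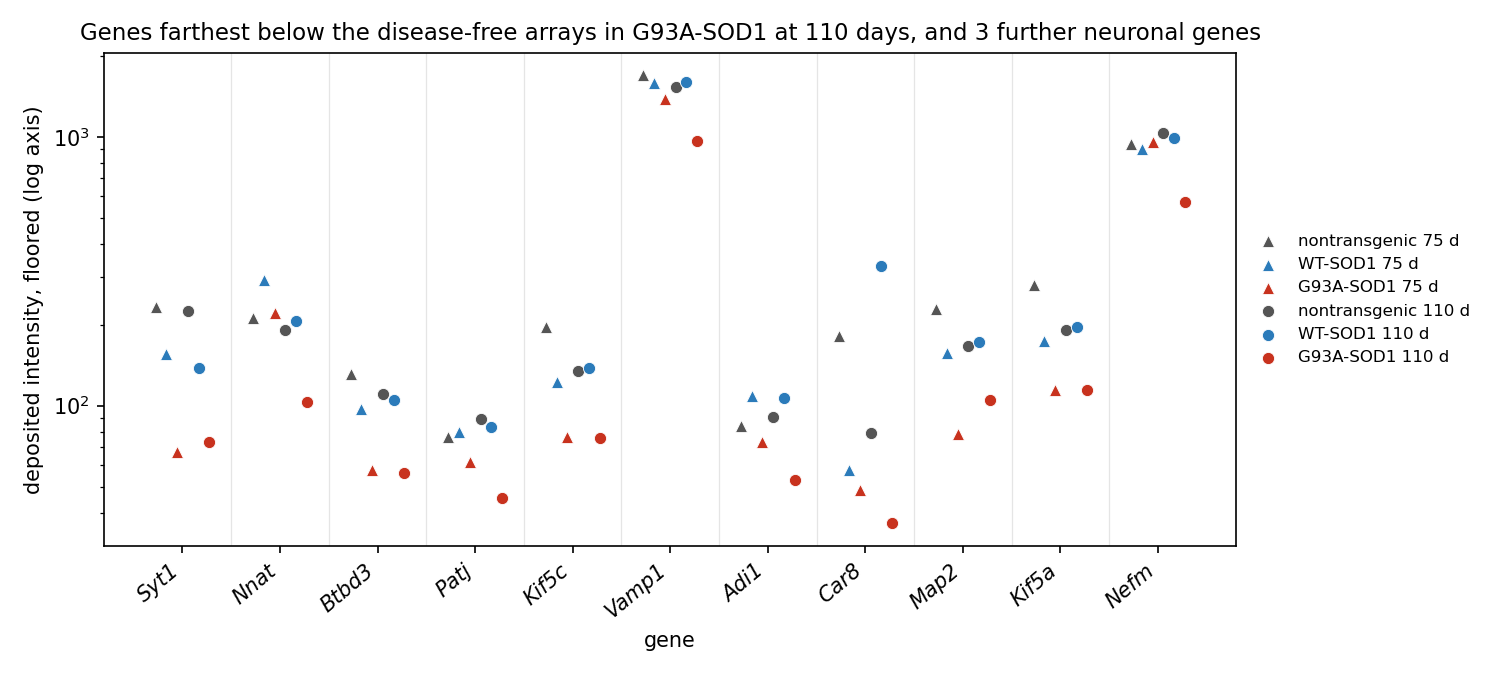
Deposited intensity after flooring (log axis) of the 8 genes farthest below the disease-free arrays at 110 days, with Map2, Kif5a and Nefm, 1 point per array, triangles for 75 days and circles for 110 days. Syt1 read 67.3 and 73.2 on the G93A-SOD1 arrays and at least 138 on the disease-free arrays, whereas Nefm was low on the 110-day G93A-SOD1 array alone.

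The remaining lists had 0 calls at 110 days over all probe sets, apart from Hspa1b, which is described with the comparison of ages. Myelin and oligodendrocyte genes (17 measured) had a median of 0.12, with Mal at -0.29 and Ugt8a at -0.28. Metal and iron handling genes (14 measured) had a median of 0.11, with the metallothionein genes Mt1 and Mt2 at 0.77 and 0.76 (adjusted p = 0.468 and 0.452). Antioxidant genes (25) had a median of 0.02, with Nfe2l2 at 0.72 and Hmox1 at 0.45. Heat shock and proteasome genes (36, 3 falling adjusted over the list alone) had a median of -0.14, and endoplasmic reticulum stress genes (16, 1 falling adjusted over the list alone) of -0.13, with Hspa5 at -0.76 and Xbp1 at -0.64. Apoptosis genes (14, 1 rising adjusted over the list alone) had a median of 0.09, with Mcl1 at 0.45. Axon injury genes (20, 1 rising adjusted over the list alone) had a median of 0.13, with Anxa2 at 0.69 and Tgfb1 at 0.65. Immediate early genes (13) stood at 0.11, with Fos at 0.78 and Dusp1 at -0.29. Cell cycle genes (20) stood at 0.15, with Ccnd1 at 0.91 and Mcm3 at 0.40. Ribosomal protein genes (18) stood at 0.11, with Rplp0 at 0.48 and Rpl10a at 0.39.

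Markers of other cell types gave 0 calls as well. Median log2 differences at 110 days were -0.03 for 7 lymphocyte genes, -0.02 for 8 neutrophil genes, -0.36 for 3 blood genes, -0.03 for 9 endothelial and vessel genes, 0.08 for 3 Schwann cell genes, -0.18 for 5 sensory ganglion genes (1 falling adjusted over the list alone), 0.08 for 13 skeletal muscle genes, 0.09 for 6 ependymal and choroid plexus genes (2 rising adjusted over the list alone) and 0.04 for 13 Hox genes. Zap70 and Ighm, the lymphocyte genes farthest from 0, stood at 0.18 and -0.16, and other probe sets of both genes had the opposite sign. For neutrophils Mmp9 stood at -0.24 and Ltf at 0.15, for blood Hbb-b2 at -0.37 and Hba-a1 at -0.36, and for vessels Tagln at 0.58 and Slc2a1 at -0.39. Sox10 (another probe set with the opposite sign) and Dhh of Schwann cells stood at 0.20 and 0.08, Sncg of ganglia at -0.22, Acta1 and Myl1 of muscle at 1.44 and 0.42, Rarres2 and Mia of the choroid list at 0.70 and 0.66, and Hoxa5 and Hoxa7 at -0.33 and 0.28. Xist, the transcript of the inactive X chromosome, was the 1 sex gene that passed the filter. It read 102 and 68.7 on the nontransgenic 75-day and WT-SOD1 110-day arrays, lay at the floor of 31 on the other disease-free arrays, and read 64.5 and 49.5 on the G93A-SOD1 arrays at 75 and 110 days.

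**Figure D3:**
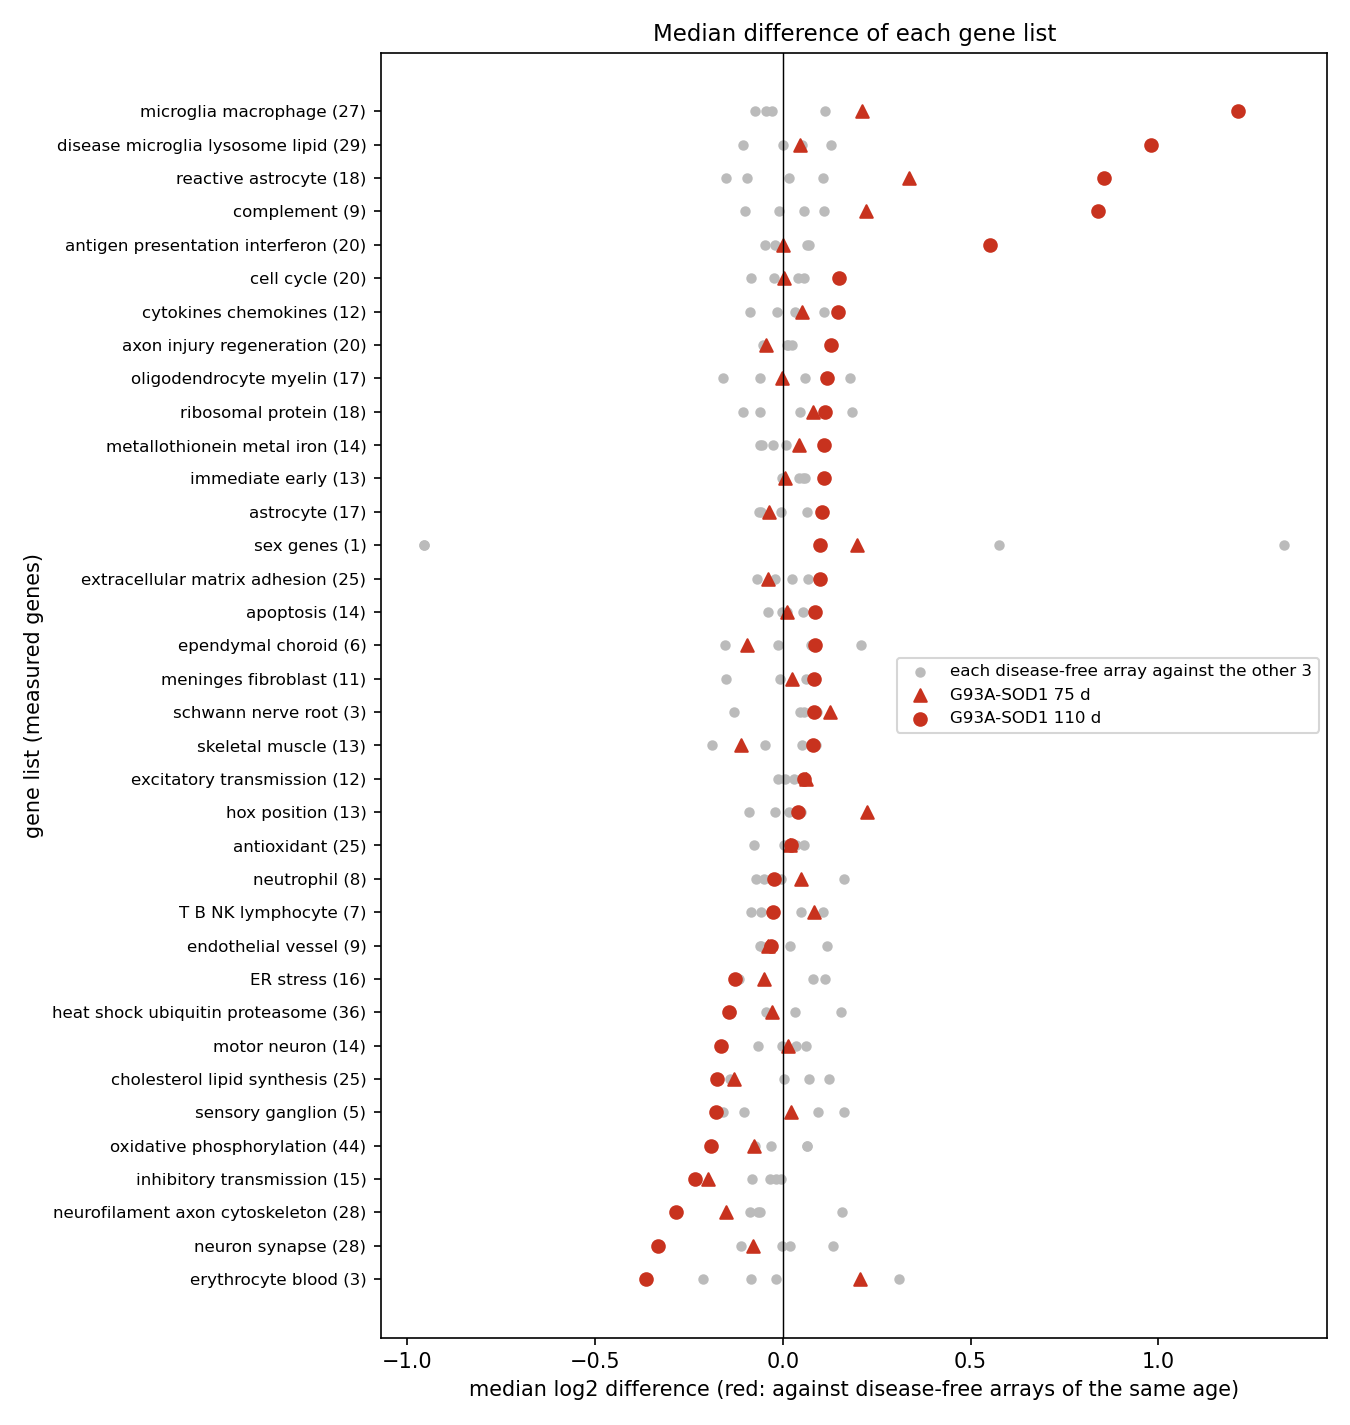
Median log2 difference of each of 36 gene lists, with the number of measured genes in brackets, for G93A-SOD1 against disease-free arrays of the same age (red triangles, 75 days, and red circles, 110 days) and for each disease-free array against the other 3 (grey). At 110 days the microglia list stood at 1.21 and the neuron and synapse list at -0.33, and the sex gene list is the single gene Xist.

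Across all probe sets, 102 differed between G93A-SOD1 and disease-free cord at 110 days, 93 higher (77 named genes) and 9 lower (9 named genes). The test was limma with Benjamini-Hochberg adjustment. By size alone, 66 to 75 probe sets of the 110-day G93A-SOD1 array lay at least 2-fold outside the range of 3 disease-free arrays, 66 to 74 of them above it. The same count for single disease-free arrays against the other 3 was 0 for both nontransgenic arrays, 7 for WT-SOD1 at 75 days and 1 for WT-SOD1 at 110 days. The bacterial spike-in probe sets averaged 549 and 740 on the nontransgenic 75-day and WT-SOD1 110-day arrays and 299 to 371 on the other 4, and a term for this difference, chosen after seeing the data, gave 266 calls (158 higher, 108 lower), while the 4 arrays with the lower levels alone gave 131 (118 higher, 13 lower). Without the nontransgenic 110-day array the count was 194, and without the WT-SOD1 110-day array 591 (199 higher, 392 lower), while it was 42 with no filter, 64 with a filter on the mean level, 66 with a floor at the 40th percentile and 78 with arrays scaled to 1 median.

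At 75 days, before symptoms in the submitters' description, 0 of 6737 probe sets passed the limma test, while 664 had an unadjusted p under 0.05 (225 higher, 439 lower). That exceeds the share of 0.05 due with no differences, but probe sets of an array are not independent. The smallest adjusted p was 0.178. Syt1 lay farthest below the disease-free range: it read 67.3 against 138 to 232 (log2 difference -1.50, adjusted p = 0.44). Next came Fmr1 at 40.8 against 82.3 to 144, and Map2, encoding a dendritic microtubule protein, at 78.5 against 157 to 229 (-1.27, adjusted p = 0.398). The transcription factor gene Zic1 read 231 against 462 to 1106, Kif1c 93.3 against 167 to 325, and Strn3 114 against 199 to 264. Zic1, Kif1c and Strn3 lay below the range by under 1 log2 unit, and the genes listed next lay above it by under 1 log2 unit. Above the range were Coasy at 150 against 58.4 to 77.3, Mrpl2 at 107 against 44.0 to 58.4, and the actin-bundling protein gene Fscn1 at 1789 against 952 to 1100. The water channel gene Aqp1 read 155 against 69.2 to 102, Cyp7b1 90.3 against 55.5 to 59.7, and Inhbc 158 against 90.4 to 106.

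None of the 36 lists had a call over all probe sets at 75 days. Adjusted over the list alone, 5 neurofilament and axon genes and 1 motor neuron gene fell, 1 heat shock and 1 blood gene rose, and among ependymal and choroid plexus genes 1 rose and 1 fell. The microglia list stood at a median of 0.21, with 24 of 27 genes above 0, against -0.07 to 0.11 for the disease-free arrays. The reactive astrocyte list stood at 0.34 (disease-free -0.15 to 0.11), with Gfap at 0.77 (adjusted p = 0.46) and S100a6 at 0.73 (adjusted p = 0.495). Complement genes stood at 0.22 and Hox genes at 0.22. Each of these 4 medians lay above at least 99.9% of matched random lists. The neuron and synapse list stood at -0.08 (percentile 24.4), within the disease-free values, while inhibitory transmission genes stood at -0.20 (percentile 1.41, disease-free -0.08 to -0.0037) and neurofilament and axon genes at -0.15 (percentile 2.89, disease-free -0.09 to 0.16). By size, 4 to 11 probe sets lay at least 2-fold outside the range of 3 disease-free arrays. At 1.5-fold, a size chosen after seeing these counts, 44 to 73 lay below the range and 10 to 21 above it. Single disease-free arrays against the other 3 then had 1 to 4 below and 3 to 35 above, most on the nontransgenic 110-day array. With 1 array left out in turn the count of calls was 13 without nontransgenic 75 days, 36 without WT-SOD1 75 days, and 116 without either of the 110-day disease-free arrays. Against nontransgenic arrays only it was 185 (26 higher, 159 lower), against WT-SOD1 arrays only 25 (4 higher, 21 lower), with no filter 50 (48 higher, 2 lower), with a WT-SOD1 genotype term 43 (6 higher, 37 lower), with the spike-in term 1, and for the 4 arrays with lower spike-in levels 0.

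The change of the G93A-SOD1 difference with age was tested directly. Among genes past the test, Lyz2 led those whose difference grew from 75 to 110 days: it was 0.02 at 75 days and 2.84 at 110 days (change 2.82, adjusted p = 0.022). Hpgd grew by 2.71 (adjusted p = 0.00668), Serpina3n by 2.19 (adjusted p = 0.022), Cst7 by 2.14 (adjusted p = 0.0281) and Mpeg1 by 2.13 (adjusted p = 0.0214). In the opposite direction, Hspa1b changed by -3.45 (adjusted p = 0.00668) and Zbtb16 by -1.59 (adjusted p = 0.0376), and these were the 2 genes of that direction. In all, 28 probe sets passed, 26 upward and 2 downward. Of the 93 probe sets that rose at 110 days, 68 had a difference above 0 at 75 days, with a median of 0.15, where 42.5% of all probe sets did. These probe sets are not independent. Both G93A-SOD1 arrays had lower spike-in levels, while the disease-free mean of each age includes an array with higher levels. An offset shared in this way could raise the 68 and was not tested. The count of probe sets whose change between ages passed was 2 with arrays scaled to 1 median, 3 with a floor at the 40th percentile, 11 with a filter on the mean level, 76 with no filter (35 upward, 41 downward), 70 with a WT-SOD1 genotype term and 90 with the spike-in term. The strain labels of the G93A-SOD1 arrays differ between these ages. Between 51 and 135 passed with 1 disease-free array left out (61 without nontransgenic 75 days, 135 without nontransgenic 110 days, 51 without WT-SOD1 75 days and 85 without WT-SOD1 110 days).

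Age was compared within the disease-free arrays, to see what differed without disease. Hspa1b, encoding the inducible chaperone Hsp70, was higher at 110 days: it read 64.7 and 54.4 on the nontransgenic and WT-SOD1 arrays at 75 days and 282 and 252 at 110 days (log2 difference 2.17, adjusted p = 0.00409). It was the 1 probe set that passed of 6737, and 209 had an unadjusted p under 0.05, fewer than the share of 0.05 due with no differences. On the G93A-SOD1 arrays Hspa1b read 137 at 75 days and 56.4 at 110 days, so that its log2 difference from the disease-free arrays was -2.24 at 110 days (adjusted p = 0.00138) although the value lay inside their range over both ages. The zinc finger gene Zbtb16 followed the same order, 151 and 150 at 75 days, 314 and 361 at 110 days, and 233 and 173 on the G93A-SOD1 arrays (age adjusted p = 0.0703). Ranked by the smaller of the differences in both genotypes, the next upward were Hspa1a (mean difference 1.04), the kinase gene Sgk1 (1.19) and the chaperone gene Hspa5 (0.86), none past the test. Of 36 heat shock and proteasome genes 1 rose with age (7 adjusted over the list alone, median 0.13), and of 16 endoplasmic reticulum stress genes 0 did (3 adjusted over the list alone, median 0.15). Downward, the same ranking gave Acta1 at -1.93, Myl1 at -0.85, Atp2a1 at -0.51, Prl at -1.92 and Cdkn1c at -0.47, none past the test, while Gh had the largest mean difference, -2.94, from the WT-SOD1 75-day array. The count was 2 without the nontransgenic 110-day array, 5 without WT-SOD1 75 days, 16 without WT-SOD1 110 days, 17 without nontransgenic 75 days, 15 with a WT-SOD1 genotype term, 6 with the spike-in term, and 0 with no filter, where Hspa1b did not pass.

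**Figure D4:**
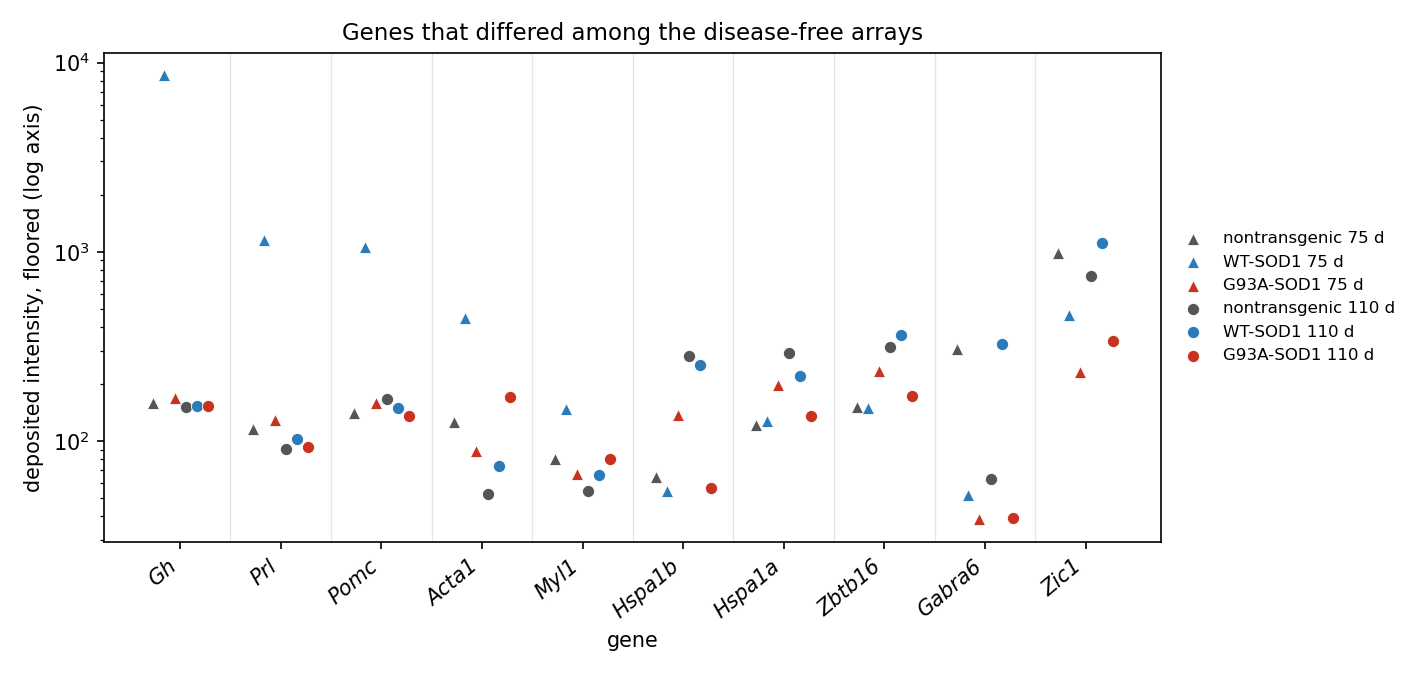
Deposited intensity after flooring (log axis) of 10 genes that differed among the disease-free arrays, 1 point per array, triangles for 75 days and circles for 110 days. Gh read 8572 on the WT-SOD1 array at 75 days and 151 to 169 elsewhere, and Hspa1b was highest on both disease-free arrays at 110 days.

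WT-SOD1 was compared with nontransgenic cord for effects of the transgene without disease. Acta1, encoding skeletal muscle actin, passed the test (log2 difference 1.16, adjusted p = 2.96e-06, but 1 with arrays scaled to 1 median), and was higher on the WT-SOD1 array at both ages, 448 against 126 at 75 days and 74.1 against 52.5 at 110 days. Pituitary hormone genes passed the test too, but stood out on the 75-day WT-SOD1 array alone. Gh, encoding growth hormone, read 8572 there and 151 to 169 on the other 5 arrays, Prl (prolactin) 1157 against 90.6 to 129, Pomc 1060 against 135 to 167, and Cga, the shared subunit of glycoprotein hormones, 286 against 70.9 to 90.9. In all 7 probe sets passed, 6 higher and 1 lower, the lower one without a single gene name. An unadjusted p under 0.05 was found for 79, fewer than the share of 0.05 due with no differences. Besides Acta1 and Sod1, the genes higher at both ages by the widest margin were Ahnak (0.44), Atp2a1 (0.43) and Cebpd (0.37), and those lower were Syt1 (-0.64), Trak2 (-0.56), Mtif2 (-0.37), Ecpas (-0.30) and Actb (-0.35), none past the test. Among 13 skeletal muscle genes 1 passed, Acta1 (2 adjusted over the list alone), with a median of 0.10 and 12 above 0. Reactive astrocyte genes had a median of 0.15 (15 of 18 above 0, percentile 100), antigen presentation genes 0.08 (17 of 20 above 0, percentile 99.7), neurofilament and axon genes -0.10 (percentile 0.06) and neuron and synapse genes -0.09 (percentile 0.24, 1 falling adjusted over the list alone). These percentiles refer to random lists and do not count the spread between arrays, given here as the SD of the disease-free arrays' medians. That SD was 0.12 for reactive astrocyte, 0.06 for antigen presentation, 0.12 for neurofilament and axon, and 0.10 for neuron and synapse genes. The medians were close in size to this SD, so they do not set a transgene effect apart from differences between arrays. Across probe sets, which are not independent replicates, the difference at 75 days and that at 110 days had Pearson's r = -0.36. The WT-SOD1 array had the lower spike-in level of its pair at 75 days and the higher at 110 days. A difference tied to that level would turn sign between the ages, which was not tested. The fit has 1 residual degree of freedom and infinite prior degrees of freedom, so that every probe set has the same SE of 0.19 and its own spread does not count, as for Acta1 with differences of 1.83 at 75 days and 0.50 at 110 days. Without the age term, with a floor at the 40th percentile or with arrays scaled to 1 median it made 0 calls, and without any 1 of the 4 arrays, the 75-day WT-SOD1 array included, it has no residual degrees of freedom and gives no test.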

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

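The lists for pituitary, glucocorticoid-responsive and clock genes were written before the levels of their members were looked at, whereas the tests of a transgene effect and of the spike-in levels, the count without the pituitary hormone genes and the reading of all clock genes were chosen only after the result was seen. All patterns weighed here were themselves picked because they were seen in these arrays. The allowance for spread in reading the glucocorticoid and clock tests was also added after the values were seen, and it changed none of the readings.

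Some single disease-free arrays stood apart from the other 3 in genes named above. Of 101 named genes 12 did so. Chance alone marks about 1 in 20 independent genes not picked by these values, or 5.05 of 101. Many named genes were picked by rules that read the disease-free values, so 5.05 is no measure of chance for them. Gfap read 2206 on the WT-SOD1 110-day array (others 1583 to 1617), Mt2 2915 there (1618 to 1683) and Rpl10a 484 (459 to 463). On the WT-SOD1 75-day array Prl read 1157 (90.6 to 116), Aqp1 102 (69.2 to 73.0) and Hpgd 51.1 (45.6 to 46.2). On the nontransgenic 110-day array Kif1c read 325 (167 to 182), Strn3 264 (199 to 208), Fmr1 144 (82.3 to 88.5), Zap70 371 (440 to 447), Inhbc 90.4 (105 to 106) and Tagln 54.6 (62.6 to 64.3). The cause of these readings was not tested, apart from that of Prl below.

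The G93A-SOD1 difference was not the same at both ages for 28 probe sets. Its change from 75 to 110 days was 2.82 for Lyz2, 2.71 for Hpgd, 2.19 for Serpina3n, 2.14 for Cst7, 2.13 for Mpeg1, -3.45 for Hspa1b and -1.59 for Zbtb16. The submitters place symptoms between these ages, and the 5 genes with growing differences include Lyz2, Cst7 and Mpeg1 of macrophages.

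Gh, Prl, Pomc and Cga, hormone genes of the anterior pituitary, were high on the WT-SOD1 75-day array alone, with a median 3.12 log2 units above the nontransgenic array of that age. Their median difference at 110 days was -0.041, which restates that the pattern lies in 1 array and tests nothing, so an effect of the transgene at 75 days stays open. RNA from pituitary tissue on that array remains a hypothesis: of the other hormone genes Lhb, Fshb and Tshb, 1 stood more than 0.3 log2 units above every other array, where at least 2 had been predicted, and this cannot tell. Lhb read 266 against at most 214, Tshb 58.0 against 48.0 and Fshb 20.1 against 17.5, the last of these under the floor. Of 19 other pituitary genes 1 stood out as far on that array, Dlk1 at 338 against 180 to 208, and 0 or 1 on each of the other arrays.

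Hspa1b, Hspa1a, Hspa5, Zbtb16 and Sgk1 were high on both disease-free arrays at 110 days and lower on the G93A-SOD1 array of that age, with a median age difference of 1.16. The spike-in levels alone could not give this pattern, since each age had an array of either level. Between arrays of the same level these genes were higher at 110 days by a median of 1.20 for the lower level (WT-SOD1 75 days to nontransgenic 110 days). For the higher level (nontransgenic 75 days to WT-SOD1 110 days) it was 1.01, and for Hspa1b the values were 2.37 and 1.96. The genes were picked for rising in both genotypes, so these values restate the pattern and are no separate test. A response to glucocorticoids at harvest might raise Zbtb16 and Sgk1, but 15 other such genes had a median age difference of 0.039 in nontransgenic mice (0.29 in WT-SOD1). The list was mixed, as 2 members picked after their values were seen show. At 75 and 110 days Fkbp5 read 127 and 149 in nontransgenic, 147 and 217 in WT-SOD1 and 215 and 150 in G93A-SOD1 mice. Cdkn1a read 250 and 212 in nontransgenic and 225 and 276 in WT-SOD1 mice. A response of some of these genes stays open. Time of day could play a part as well, yet among the 3 of 5 clock genes named beforehand that passed the filter, and among all 8 tested clock genes, the largest difference shared by both genotypes was 0.18. Age itself and the handling of the mice at harvest remain possible and were not tested, so the fall of Hspa1b in G93A-SOD1 cord at 110 days rests on what the disease-free arrays of that age show.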

How the results depend on the processing

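Settings named for the spike-in levels were chosen only after the result was seen, and all others before the data were examined. Each count is of probe sets past the threshold. G93A-SOD1 at 110 days, with 102 in the report, had 66 with the floor at the 40th percentile, 42 with no filter, 64 with the filter on the mean, 183 against nontransgenic arrays only, 170 against WT-SOD1 arrays only, 266 with the term for the spike-in group, and 148 to 591 with 1 array left out. At 75 days, with 0, there were 50 with no filter, 1 with disease-free arrays as one group, 185 and 25 against nontransgenic or WT-SOD1 arrays only, 43 with a WT-SOD1 genotype term, 1 with the spike-in term, and 13 to 116 with 1 array left out. The change between ages, with 28, had 2 under log2 median centring (1 higher, 1 lower), 3 with the floor at the 40th percentile, 76 with no filter, 11 with the filter on the mean, 70 with the genotype term, 90 with the spike-in term, and 51 to 135 with 1 array left out. Age, with 1, had 0 with no filter, 15 with the genotype term, 6 with the spike-in term, and 2 to 17 with 1 array left out. WT-SOD1 against nontransgenic, with 7, had 0 under log2 median centring, the floor at the 40th percentile, no filter and no age term, and was not run with 1 array left out for lack of residual degrees of freedom. Probe sets at least 2-fold outside the range numbered 45 at 110 days with the filter on the mean. At 75 days they numbered 3.5 on average under median centring, 4 with the floor at the 40th percentile, and 4 to 11 with 1 array left out. With no filter, 2882 of 12422 probe sets had no spread at all among disease-free arrays, which dropped the prior degrees of freedom to 0.41, and 34 of the 36 called values for named genes were lost. The floor at the 40th percentile lost 12 and median centring 9. No call for a named gene was lost with 1 array left out, where this could be run. These reruns made more calls in every comparison, so they could hardly lose one. Values turned sign for 5 genes, none past the threshold. Against WT-SOD1 arrays only, Acta1 at 110 days was -0.10, Dhh -0.058, Myl1 -0.30 and Sod1 -0.018. With disease-free arrays as one group Myl1 was -0.00760 and Xist -0.043, and with lower spike-in arrays only Myl1 was -0.16. Sod1 was -0.044 with the spike-in term, and Xist -0.14 with the floor at the 40th percentile and -0.19 against nontransgenic arrays only. Without the nontransgenic 110-day array Dhh was -0.095, Sod1 -0.15 and Xist -0.47. Without the WT-SOD1 110-day array these were 0.26, 0.20 and 0.67. Apart from the missing filter, the cause was not tested. The list medians at 110 days, the only ones rerun, moved by more than the SD of the disease-free arrays' medians in 39 cases and by less in 356. With no filter microglia genes stood at 0.63, reactive astrocyte genes at 0.54, complement and antigen presentation genes both at 0.38, lysosomal and disease-associated microglial genes at 0.88, metal handling genes at 0.05, cytokine and axon injury genes both at 0.06, motor neuron genes at -0.05, inhibitory transmission genes at -0.19, blood genes at -0.09, and apoptosis and excitatory transmission genes at 0. The filter on the mean gave 0.48 for antigen presentation and 0.76 for disease-associated microglial genes, which stood at 0.88 with the floor at the 40th percentile, and quantile normalization gave -0.17 for inhibitory transmission. The median over all probe sets of a gene gave 0.77 for disease-associated microglial, 0.17 for axon injury and 0.0096 for excitatory transmission genes. Without the nontransgenic 110-day array the medians were 1.13 for microglia, 0.67 for complement, -0.19 for neuron and synapse, -0.11 for motor neuron, 0.21 for metal handling, 0.17 for axon injury, 0.07 for immediate early, -0.05 for cholesterol and lipid, -0.06 for meninges, -0.15 for neutrophil and -0.00866 for excitatory transmission genes. Without the WT-SOD1 110-day array they were 1.30 for microglia, 1.14 for reactive astrocyte, -0.45 for neuron and synapse, -0.23 for motor neuron, 0.09 for axon injury, -0.31 for cholesterol and lipid, 0.22 for meninges and 0.10 for neutrophil genes. No paired analysis was possible because the labels give no replicate numbers, and the arrays are matched only by age, which enters the fits. Signal close to background limits what can be read from genes near the floor of 31, such as Xist, which lay at the floor on 2 disease-free arrays.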

Other observations

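The genes in the next paragraphs fall outside the naming rule and were chosen only after the result was seen, as were the test of the share of neurons and the 5 genes it concerns. The cerebellar and Y-linked lists were written before the levels of their members were looked at.

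Some genes outside the lists also rose at 110 days, and are given here as single genes. Log2 differences were 1.72 for Anxa3, 1.66 for Apbb1ip, 1.17 for Lgals1, 1.16 for S100a4 and 1.07 for Msn. A2m, encoding alpha-2-macroglobulin, rose by 1.44, Plat, encoding tissue plasminogen activator, by 1.24, Pros1, encoding protein S, by 1.23, and Klk6 by 1.14. Nupr1 rose by 1.52 and the growth factor gene Hbegf by 1.43. Lower at 110 days were Sema7a, a semaphorin gene, at -1.20 (adjusted p = 0.0248, another probe set with the opposite sign), Ddx17 at -0.99, the transporter gene Slc38a2 at -0.84, and Max and Mxd4, which encode partners in the Myc network, at -0.90 and -1.14.

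Among lysosomal protease genes of the lists, Ctsz, Ctss, Ctsh, Ctsd and Ctsb rose 3.86-fold, 2.84-fold, 2.78-fold, 2.49-fold and 1.84-fold, while Ctsl at 1.57-fold (adjusted p = 0.0922) and Lgmn at 1.28-fold (adjusted p = 0.607) did not pass. Csf1r, encoding the receptor for macrophage colony-stimulating factor, rose 2.58-fold. Nes, encoding nestin, rose 2.16-fold among genes of reactive astrocytes.

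Syt1, Btbd3, Kif5c, Kif5a and Map2 lay at least 0.5 log2 units below all disease-free arrays at both ages of G93A-SOD1 (median fall -1.03 at 75 days and -0.85 at 110 days, none past the test), and 0 genes lay as far above. A smaller share of neurons stays open. At 75 days 27 other neuron and synapse genes had a median of -0.042, and the inhibitory transmission and neurofilament lists -0.20 and -0.15. Neuronal genes in general thus fell less than Syt1 and the genes named with it, and a small general fall stays open. However, Syt1 and the genes named with it were picked for their low values on these arrays. Genes not picked in this way would lie higher under any cause, so this comparison cannot tell what lowered the picked genes. Lower RNA integrity remains open: disease-free arrays with higher 3' to 5' ratios gave -0.29 for these genes but 0.068 for Syt1, these arrays also had low cerebellar medians and spike-in levels, and on the G93A-SOD1 arrays at 75 and 110 days only the Gapdh ratios of 1.49 and 1.30 lay above the disease-free range (1.08 to 1.27), while those of actin (1.998 and 1.904, range 1.69 to 2.39) and pyruvate carboxylase (3.93 and 3.74, range 2.90 to 4.23) lay inside and those of the transferrin receptor (3.21 and 3.80, range 3.67 to 4.36) lay below and inside, so this cannot tell. Less brainstem or cerebellar tissue is a hypothesis, as 11 cerebellar genes had medians of -0.31 and -0.41 on the G93A-SOD1 arrays at 75 and 110 days, but on the disease-free arrays these were 0.22 (nontransgenic 75 days), -0.22 (nontransgenic 110 days), -0.24 (WT-SOD1 75 days) and 0.13 (WT-SOD1 110 days). In the same order of disease-free arrays the most abundant marker, Pvalb, read 2968, 2678, 3034 and 2931, and 2614 and 2186 on the G93A-SOD1 arrays, Nrep 819, 529, 555 and 760, and 553 and 380, and Cbln1 697, 485, 415 and 656, and 297 and 274.

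The sex of the mice was not settled by the Y-linked genes, which read close to the floor of 31. Before flooring, Eif2s3y read 41.2 and 38.6 on the nontransgenic 110-day and WT-SOD1 75-day arrays, where Xist read 19.6 and 18.6, and 22.6 to 32.0 on the other 4 arrays, where Xist read 49.5 to 102. Uty read 39.4 and 24.3 on the former arrays and 21.9 to 29.0 on the others, and Kdm5d at most 25.6 throughout. The G93A-SOD1 differences at 75 and 110 days had Pearson's r = 0.34 across probe sets, which are not independent replicates, and the comparisons at these ages use separate arrays. However, the disease-free mean of each age includes an array with higher spike-in levels, and both G93A-SOD1 arrays had lower levels. An offset shared in this way could raise r and was not tested.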
